A study of Mus musculus with 20 samples.

How the data were processed

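The samples were 20 Affymetrix MOE430 2.0 arrays, single-colour oligonucleotide arrays that measure a transcript with a set of short probes near its 3′ end. Per the labels' protocols, RNA came from the frozen cardiac ventricle of male C57BL/6J mice, was extracted with Trizol and RNeasy columns and hybridised as biotin-labelled material. Groups were taken from the sample titles, which mark each array as old or young and number them from 1 to 20; the protocols give 4 to 6 months for young and 25 to 28 months for old mice. The design text of the series calls both age ranges young, which was read as a slip since the titles and protocols separate them. No replicate number is shared between the groups.

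The deposited table holds 1 value per probe set and array on a log2 scale. Per the submitters' processing notes the values came from GCRMA, which corrects background by probe sequence, normalizes between arrays and summarises each probe set; its version and the log base are not given in the sources used here. The log2 scale was read from the values, which run from 0.98 to 16.0. GCRMA places transcripts that are not detected near a common low value, so differences of dim genes are compressed or, once a gene leaves that floor, steep, and very bright probe sets approach saturation. The table had 45101 probe sets, of which 64 were controls, and all 20 columns were used.

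Probe sets were named through the platform annotation supplied with the table and updated by gene identifier to a gene table of the GRCm38.p6 assembly, which was used for names alone. In the annotation 34945 probe sets had 1 gene, 932 had several and 9160 others were unnamed here; 34754 had an identifier in the gene table. Probe sets with several genes or none entered neither the gene-level tests nor the text. A probe set passed the filter when its log2 value exceeded 4 in at least 10 of the 20 arrays. One that was under 4 in every young array thus passed only when every old array exceeded 4. In marker lists with few tested members, the filter therefore favours genes that rise. Each gene was represented by its passing probe set with the highest mean over all 20 arrays, which gave 9275 genes.

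Old and young were compared with limma (version 3.58.1; lmFit and eBayes in R 4.3.3), with no covariate and Benjamini-Hochberg adjustment over all genes tested, and an adjusted p under 0.05 was required. The adjusted p of a gene is from this fit unless another is named. Fold sizes are log2 differences, old minus young. 43 gene lists for heart tissue, mitochondria, ageing and the other cell types of the heart, with 1113 entries, were written before the data were examined, as were the groups, the tests, the filter and the first set of other settings. Of the entries, 1000 were matched to the array, 22 of them by an older symbol. A list needed 3 tested members; 40 lists had them, and the mitochondrial DNA list (1 tested member), the T and natural killer cell list (2) and the lung and thymus list (2) did not. Lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, with fry, and with a two-sided permutation test of the list's mean log2 value per array (100000 resamples), with Benjamini-Hochberg adjustment over the 40 lists. The smallest p these resamples can give is 1e-05. Camera compares a list with the other genes, fry tests whether its genes move one way, and the permutation test treats the animal as the replicate.

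The nuclear respiratory chain score is the mean log2 value of the 75 tested genes of the lists for complexes I to V. The mitochondrial DNA score rests on 1 gene. The score of all nuclear mitochondrial lists adds 6 further lists and was formed after the data were seen. The named genes are, by a rule fixed before the data were examined, the 8 largest rises and 8 largest falls among called genes, 14 fixed genes of heart ageing, and up to 4 members with the smallest p of each list described, taken in order of p whatever their direction. Genes outside that rule are named as chosen after their values were seen.

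After the values were seen, 2 structures were added as alternatives. The atrial index is the mean over Myl7 and Sln of the linear value divided by that gene's highest array. The array sets come from average linkage clustering of 1 minus the Pearson correlation of residuals from the group means, divided into 5 sets, the number with the highest mean silhouette (0.35) among 2 to 8 (cluster 2.1.8.1). Scores were tested with the index by permuting residuals of the reduced model (Freedman-Lane, 100000 resamples), within sets by exact enumeration of 7776 arrangements, and without the 7 old arrays with Myl7 above 10 by exact enumeration of 286. The sets were found on the values that were then tested, so the block makes p-values somewhat too small. Other settings fixed beforehand were quantile normalization and median centring of the arrays, no filter and a filter at 6, the mean of a gene's passing probe sets, leaving out probe sets of the _x_at, _s_at and _a_at kinds, every probe set tested on its own, eBayes with trend and robust settings, array weights, an RNA quality covariate, a fold of at least 1.5, an adjusted p under 0.01, median absolute deviations for the spread, and leaving out each array in turn.

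The code was tested on simulated data for the old against young comparison, drawn from the means and residual spreads of the 9275 genes. Of 67 genes changed 1.25-fold 14.9% were recovered, of 67 changed 1.5-fold 64.2% and of 66 changed 2-fold 92.4%, with 1 false call among the unchanged genes. These simulated genes vary independently, so list tests on them do not carry the correlation between real genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.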

Results

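The series asked whether expression of mitochondrial genes declines with age in the mouse heart. Total RNA from the cardiac ventricle of 20 male C57BL/6J mice, an inbred laboratory strain, was hybridised to Affymetrix MOE430 2.0 arrays, 1 array per mouse. The old group held 10 mice of 25 to 28 months and the young group 10 mice of 4 to 6 months. The deposited values are GCRMA signals on a log2 scale, with array medians between 3.07 and 3.20. RNA quality, read as the 3′ minus 5′ difference of the Gapdh and β-actin control probe sets, was 0.40 ± 0.10 in old and 0.39 ± 0.08 in young (SD, n = 10 each; two-sided permutation test, p = 0.921). The share of probe sets above a log2 value of 4 was 38.7% ± 0.60 in old and 38.1% ± 0.18 in young (SD, n = 10 each; permutation p = 3e-05, adjusted p = 0.00015). No 2 arrays held identical values, and Spearman correlations between arrays ran from 0.885 to 0.992. The number of arrays limits the precision.

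The old hearts differed from the young ones in a large part of the measured transcriptome. Immune cell, complement, matrix, valve and platelet genes were higher in old, while genes for mitochondrial proteins and inducible heat shock genes were lower. Of 9275 genes tested, 1732 changed with age in the limma fit, 1037 higher and 695 lower in old. The largest rises were those of Myl4, an atrial myosin light chain, Car3, a carbonic anhydrase abundant in fat and skeletal muscle, Lgals3, a galectin of activated macrophages, Cxcl13, a B cell chemokine, Clec1b, a platelet receptor, Vsig4, a receptor of resident macrophages, Ccl8, a monocyte chemokine, and Ppbp, a platelet chemokine precursor. Their log2 changes ran from 7.37 for Myl4 down to 3.53 for Ppbp. Some start near the floor, with young means of 3.56 for Car3, 3.16 for Clec1b and 3.27 for Ccl8, so sizes and order are rough. Ccl8 rose from 3.27 ± 0.52 to 6.89 ± 0.54 (SD, n = 10 each, adjusted p = 5.49e-10), and every old array lay above every young one for Ccl8, Lgals3, Cxcl13, Clec1b and Vsig4. The largest falls were those of the inducible heat shock genes Hspa1b (−3.25), Hspa1a (−3.17) and Dnajb1 (−1.34), the nuclear receptors Nr4a1 (−1.98) and Nr4a2 (−1.31), the interferon-induced chemokine Cxcl9 (−1.97), Bex1 (−1.46) and Nrn1 (−1.44). Cxcl9 was 4.02 ± 0.65 in old and 5.99 ± 0.56 in young (SD, n = 10 each, adjusted p = 1.02e-05). The balance of rises and falls depended on the scaling between arrays. Of the calls, 59.9% were rises with the values as deposited, 43.1% (812 of 1884) after quantile normalization and 41.0% (779 of 1898) after centring each array on its median.

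Transcripts of atrial muscle were high in most old arrays and in none of the young ones, although the labels give ventricle for both groups. Myl7, the atrial regulatory myosin light chain, was 2.41 ± 0.02 in young and 11.41 ± 4.23 in old (SD, n = 10 each), with old arrays between 2.36 and 14.55. Sln, which encodes sarcolipin, an atrial inhibitor of the calcium pump, was 2.09 ± 0.10 in young and 10.34 ± 4.21 in old. Both genes were above 4 in 9 old arrays and in 0 young ones, too few for the gene test, and they were chosen after their values were seen. Their permutation p-values were 0.00011 and 6e-05 (adjusted p = 0.000235 and 0.00016 over 32 transcripts examined this way). Among the 9 tested members of the atrial and conduction list, 7 rose and 0 fell (7 and 1 adjusted over the list alone), with a mean log2 change of 1.76 (camera adjusted p = 0.000388; adjusted p = 0.196 with an estimated correlation). Myl4 rose by 7.37 ± 1.12 (SE), Stard10 by 2.08 and the transcription factor gene Tbx5 by 1.66. An index of these transcripts, the mean of Myl7 and Sln on the linear scale relative to their highest array, was 0.403 to 1.0 in 6 old arrays, 0.126 in old replicate 3 and at most 0.011 in old replicates 1, 2 and 7. With this index as a covariate, 347 genes were called (261 higher, 86 lower); the index term itself called 72 of 9275 genes, and 99.6% of the 1732 kept their sign. Without the 7 old arrays in which Myl7 exceeded 10, 272 were called (209 higher, 63 lower), and 252 of them were among the 1732. The 1732 genes were called on these same arrays, so the kept signs and the shared calls are no independent support. The index was high only in old arrays, so the fit separates it poorly from age. Both alternatives were chosen after seeing the data. Values under them are given below with the gene lists. The atrial list itself was at 0.58 with the index and 0.30 without the 7 arrays, no longer called (adjusted p = 0.172 and 0.524), and at 0.38 to 2.81 in the array sets described next. The index uses Myl7 and Sln and the 7 arrays were chosen by Myl7, so the loss of this list follows from their construction.

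**Figure D1:**
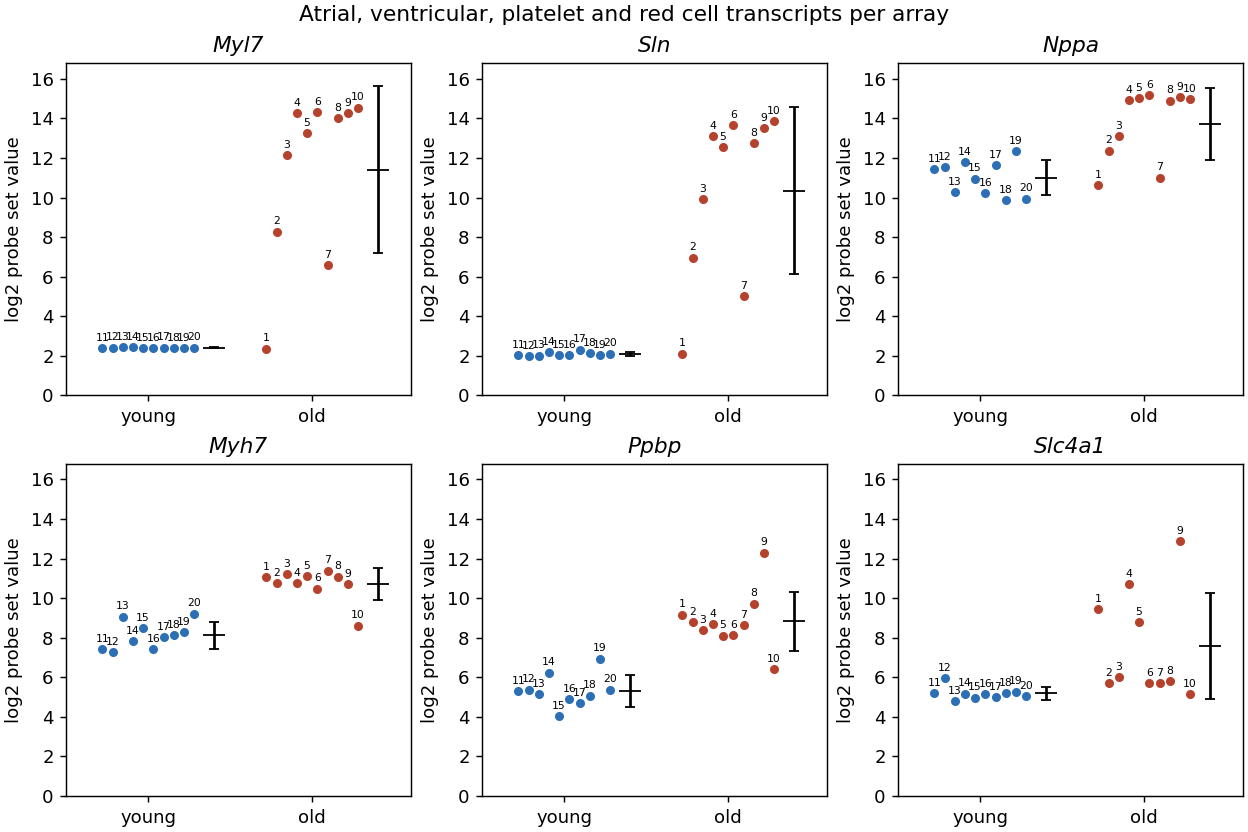
Each point is 1 array, numbered by replicate, with the log2 probe set value on the vertical axis and the group on the horizontal axis; the bar beside each group gives the mean ± SD (n = 10). Myl7 and Sln were above 4 in 9 old arrays and in 0 young ones, Myh7 was above the highest young array in 9 of 10 old arrays, Ppbp in 9 and Slc4a1 in 5.

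A second structure crossed the age groups. When the arrays' deviations from their group means were clustered, they fell into 5 sets of 4 arrays, each with 2 old and 2 young ones. All 20 arrays had their closest array inside their own set, and the mean correlation of deviations was 0.40 within sets and −0.13 between them. Of the variance of 30 spike-in control probe sets within the age groups, a median of 57.6% lay between these sets, against at most 47.9% in 1000 random sets of the same shape. The labels name no batch, so the sets are a reading of the data. They follow the numbers in the titles in part. Old replicates 1 and 2, 3 and 4, 5 and 6, 7 and 8, and 9 and 10 each shared a set. So did young replicates 12 and 13, 15 and 16, and 18 and 19, while young 11 shared a set with 20 and 14 with 17. The spike-in probe sets took no part in the clustering, so the sets also showed in control signals that the clustering did not use. Beyond this, what the sets stand for was not tested. With the set as a block, 3344 genes were called (1798 higher, 1546 lower), including all 1732, and the range of a list over the sets is given beside its shift. Without the 7 arrays, the old arrays left come from 2 of the sets and the young ones from all 5. Values without the 7 arrays may therefore also carry differences between sets.

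**Figure D2:**
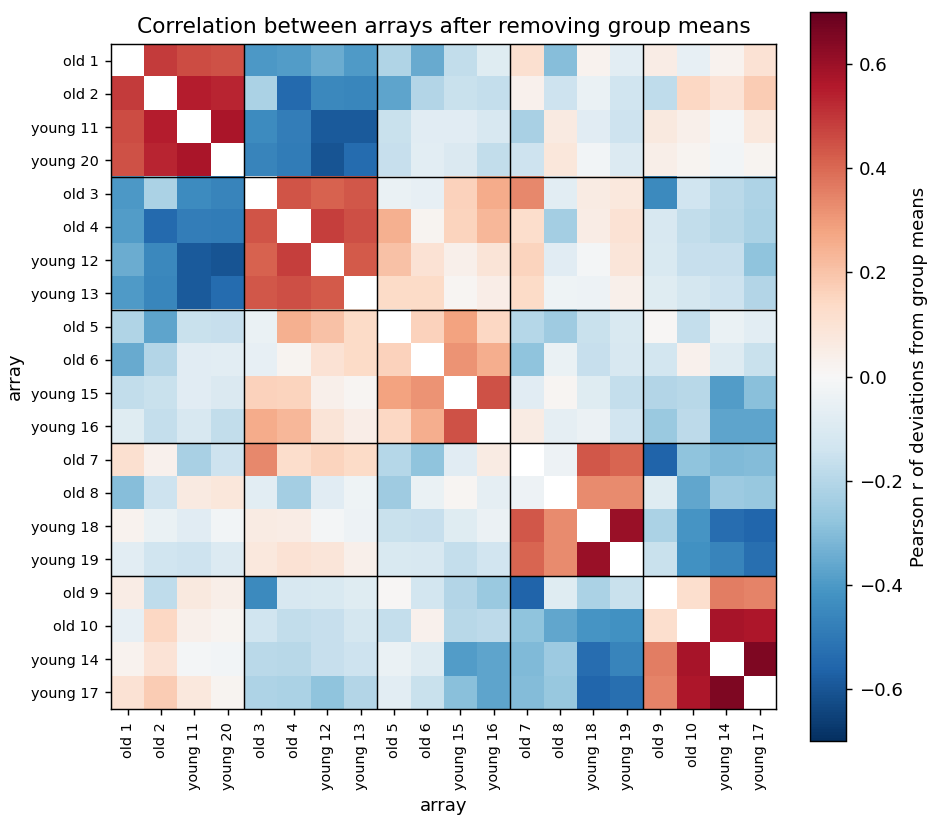
The colour gives Pearson's r between the deviations of 2 arrays from their group means over 9275 genes, with arrays on both axes and the diagonal left blank. The black lines part the 5 sets of 4 arrays; the mean r was 0.40 within sets and −0.13 between them.

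Nuclear genes of the mitochondrial lists, which also hold some regulators and fuel uptake genes whose proteins lie outside mitochondria, were lower in old hearts as a group. Of 267 genes, 71 passed the gene test as lower. A score over all of them was formed after the data were seen, while the respiratory chain score given next was planned. Over 267 such genes of 11 lists, the mean log2 value per array was 10.72 ± 0.13 in old and 10.93 ± 0.07 in young (SD, n = 10 each), a difference of −0.21 ± 0.05 (SE; two-sided permutation test, p = 2e-05). This is 13.6% lower on the linear scale. Of the 267 genes, 250 had an estimate below 0 and 2 rose. The score was lower in old in each of the 5 sets, by −0.13 to −0.33 (exact permutation within sets, p = 0.000514). With the atrial index as a covariate the difference was −0.15 ± 0.06 (SE; permutation p = 0.0187), and with the index and the sets together −0.11 ± 0.06 (p = 0.0736). Without the 7 old arrays it was −0.12 (3 old against 10 young, exact permutation p = 0.0245, smallest p possible 0.0035). The 3 old arrays left come from 2 of the sets. Matched within those sets, with 3 old and 4 young arrays, the difference was −0.09 (exact permutation p = 0.167, smallest p possible 0.0556). In the gene test, 143 of the genes fell with the set block, 2 with the index and 3 without the 7 arrays.

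The nuclear-encoded genes of the respiratory chain, which carries electrons to oxygen and makes ATP, had a mean log2 value of 13.16 ± 0.12 in old and 13.31 ± 0.07 in young (SD, n = 10 each). Over 75 genes the difference was −0.15 ± 0.04 (SE; two-sided permutation test, p = 0.00044), and 73 estimates were below 0. It lay between −0.07 and −0.25 in the 5 sets (exact permutation within sets, p = 0.000514). The difference did not pass the test with the atrial index (−0.11 ± 0.06, SE; permutation p = 0.068) or without the 7 old arrays (−0.08; exact permutation p = 0.0979). The complexes differed. Complex I, which oxidises NADH, fell by 0.20 on the log2 scale, with 9 of 32 genes lower and 0 higher (12 and 0 adjusted over the list alone; −0.10 to −0.31 in the sets; camera adjusted p = 4.63e-08; adjusted p = 0.26 with an estimated correlation). Ndufs4 fell by 0.37, Ndufb5 by 0.26 and Ndufa9 by 0.26, the last with 9 of 10 old arrays below all young ones. Complex II fell by 0.21 with 1 of 4 genes called, the succinate dehydrogenase subunit gene Sdha at −0.25 (adjusted p = 0.0466). That call was lost in 14 of the 20 fits that left out 1 array. Complex III fell by 0.18 with 2 of 10 genes called, Uqcrc1 (−0.42) and Cyc1 (−0.22). Complex V fell by 0.11 with 1 of 16 genes called, Atp5k (−0.23, adjusted p = 0.0334), a call lost in 6 of those 20 fits. The camera adjusted p-values of complexes II, III and V were 0.0222, 0.00497 and 0.0097, and 0.196, 0.256 and 0.314 with an estimated correlation. Their ranges in the sets were −0.11 to −0.36, −0.06 to −0.31 and −0.05 to −0.20. Complex IV, cytochrome c oxidase, was at −0.04 (−0.08 to 0.001 in the sets; camera adjusted p = 0.184), with Cox7a1 lower (−0.39) and Cox6a1, the isoform of tissues other than muscle, higher (0.46). Of the 13 complex IV genes, 11 had an estimate below 0. The shift of complex I differed from that of complex IV by −0.16 (permutation test, adjusted p = 0.001 over 10 pairs of complexes). In the same test complexes I, II and III did not differ from one another (adjusted p of 0.389 to 0.827). The other pairs did, with adjusted p of at most 0.0428. Complex I kept its list call with the atrial index (shift −0.16, adjusted p = 7.64e-06) and without the 7 arrays (−0.11, adjusted p = 0.00154). Complexes II (−0.13 and −0.09), III (−0.11 and −0.07) and V (−0.09 and −0.06) did not, with adjusted p between 0.0512 and 0.376. After quantile normalization complexes II and V were not called either (adjusted p above 0.05).

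Of the 13 respiratory chain genes encoded in mitochondrial DNA, 1 was named and tested, mt-Nd5, a complex I subunit. Its log2 value was 15.26 ± 0.08 in old and 15.33 ± 0.04 in young (SD, n = 10 each), a difference of −0.07 (permutation p = 0.0207; limma adjusted p = 0.448 over all genes). The size depended on the scaling, with the mtDNA-encoded respiratory chain score at −0.03 (p = 0.444) after quantile normalization and −0.14 (p = 1e-04) after median centring. The probe set was read near the top of the scale. The nuclear minus mt-Nd5 score differed by −0.09 between the groups (permutation p = 0.155), and within sets the exact p was 0.0298.

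**Figure D3:**
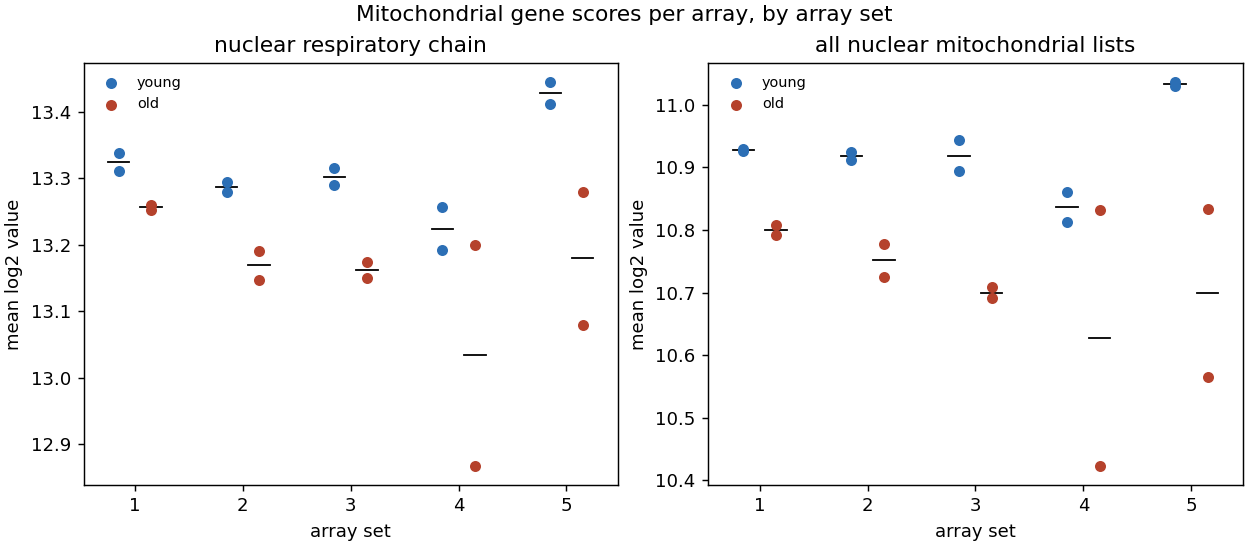
Each point is 1 array, with the mean log2 value of its genes on the vertical axis, the array set on the horizontal axis and the short lines as means of 2 arrays. The left panel holds 75 nuclear respiratory chain genes and the right panel 267 genes of all nuclear mitochondrial lists; the old mean lay below the young mean in all 5 sets in both panels.

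Fatty acid oxidation, the main fuel pathway of the adult heart, showed the largest mean fall of the mitochondrial lists. The margin over the next lists was small and not tested, and the order of the lists varied between the sets. Of 28 genes, 13 fell and 0 rose (19 and 0 adjusted over the list alone), with a mean of −0.28 (camera adjusted p = 4.63e-08; adjusted p = 0.158 with an estimated correlation) and −0.18 to −0.35 in the sets. Eci1, an enoyl-CoA isomerase, was 11.39 ± 0.32 in old and 12.03 ± 0.09 in young (SD, n = 10 each, adjusted p = 0.000243). Cpt2, a carnitine palmitoyltransferase, was 10.69 ± 0.28 in old and 11.28 ± 0.13 in young (adjusted p = 0.000372), and all 10 old arrays lay below all young ones for both genes. Mlycd, malonyl-CoA decarboxylase, fell by 0.72 and Acaa2 by 0.45. The tricarboxylic acid cycle and pyruvate dehydrogenase list fell by 0.25, with 7 of 23 genes lower and 0 higher, among them Fh1 (−0.35), Suclg1 (−0.31), Sucla2 (−0.29) and Pdhb (−0.32). The mitochondrial ribosome fell by 0.26, with 22 of 73 genes lower and 0 higher (33 and 0 adjusted over the list alone), including Mrpl1 (−0.53) and Mrps35 (−0.50). Import and chaperone genes fell by 0.19 with 8 of 30 genes called, including the chaperonin gene Hspd1 (−0.34) and Dnaja3 (−0.40). In the sets these 3 lists lay at −0.18 to −0.35, −0.15 to −0.53 and −0.09 to −0.34. The camera adjusted p-values of these 3 lists were 2.53e-06, 3.92e-11 and 6.01e-05, and 0.195, 0.314 and 0.196 with an estimated correlation. With the atrial index the shifts were −0.23 for fatty acid oxidation, −0.19 for the cycle, −0.20 for the ribosome and −0.13 for import, and without the 7 arrays −0.20, −0.17, −0.13 and −0.12. All 4 lists kept their camera call under both, with adjusted p of at most 0.0145. These calls are at the preset correlation, and no permutation test per animal is given for single lists under either. With the index and the sets together, import lost it (−0.05, adjusted p = 0.124), and the ribosome was at −0.10, the cycle at −0.22 and fatty acid oxidation at −0.23, all 3 still called.

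Regulators of mitochondrial biogenesis fell by 0.20 as a list (4 of 22 genes lower, 0 higher; −0.11 to −0.28 in the sets; camera adjusted p = 0.0028; adjusted p = 0.196 with an estimated correlation), with the mitochondrial RNA polymerase gene Polrmt at −0.47, Tfb1m at −0.63, the retinoid receptor gene Rxra at −0.41 and the deacetylase gene Sirt3 at −0.42. The coactivator gene Ppargc1a was at −0.37 (adjusted p = 0.155), Tfam at −0.09 (adjusted p = 0.562) and Esrra at −0.01 (adjusted p = 0.973), and these 3 did not pass the test. Ppargc1a passed with the set block (adjusted p = 0.0234). With the atrial index and without the 7 arrays the list was at −0.10 in both and no longer called (adjusted p = 0.098 and 0.126), while with index and sets together it was called (−0.14, adjusted p = 0.0175). Of 16 genes for mitochondrial dynamics and mitophagy, 3 fell, led by the protease gene Oma1 (−0.43), and 1 rose, the mitophagy receptor gene Bnip3 (0.55). That list was called by camera (adjusted p = 0.0404; adjusted p = 0.314 with an estimated correlation), and its score did not pass the permutation test (adjusted p = 0.0826). It ran from 0.003 to −0.17 in the sets. It was not called with the set block (adjusted p = 0.0657), with the index (−0.03, 0.293), without the 7 arrays (−0.05, 0.303) or after quantile normalization, and 6 of the 20 fits that left out 1 array lost it.

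Macrophage and complement genes rose together. Of 29 macrophage and monocyte markers, 23 rose and 0 fell (26 and 0 adjusted over the list alone), by a mean of 1.004 (camera adjusted p = 7.11e-18; adjusted p = 0.124 with an estimated correlation). The score was higher in old in each of the 5 sets, by 0.78 to 1.40. Ccl6 rose by 1.74, and Lyve1, a hyaluronan receptor of resident heart macrophages and lymphatic vessels, was 8.79 ± 0.35 in old and 7.30 ± 0.48 in young (SD, n = 10 each, adjusted p = 4.94e-06). The shift was 0.90 with the atrial index and 0.96 without the 7 arrays. Of 11 complement genes, 10 rose and 0 fell, by a mean of 0.74 (camera adjusted p = 9.82e-09; adjusted p = 0.124 with an estimated correlation), including C1qb (0.89), C1s1 (0.93) and the inhibitor gene Serping1 (0.79), with a list shift of 0.56 to 0.94 in the sets, 0.51 with the index and 0.50 without the 7 arrays. Antigen presentation genes rose by 0.44 (4 of 12 called, Tap2 at 0.53 and H2-K1 at 0.62; 9 adjusted over the list alone; camera adjusted p = 0.00157; adjusted p = 0.299 with an estimated correlation), and their shift was 0.31 to 0.60 in the sets, 0.16 with the index (adjusted p = 0.293) and 0.08 without the 7 arrays (adjusted p = 0.533). Neutrophil and mast cell markers rose by 1.79 with 3 of 4 genes called (camera adjusted p = 0.00261; adjusted p = 0.196 with an estimated correlation), among them Lcn2 (2.25) and S100a9 (2.45). Their shift was 1.20 to 2.08 in the sets, 1.70 with the index and 1.55 without the 7 arrays. Only 4 of 18 listed neutrophil and mast cell markers were tested.

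Extracellular matrix genes rose as a group. Of 39 collagen and matrix genes, 21 rose and 0 fell (22 and 1 adjusted over the list alone), by a mean of 0.67 (camera adjusted p = 9.82e-09; adjusted p = 0.196 with an estimated correlation). Mmp3, a matrix metalloproteinase, rose by 2.82, the proteoglycan gene Fmod by 3.44, Postn by 1.70 and the metalloproteinase inhibitor gene Timp3 by 0.93. Col1a1 was at 0.40 (adjusted p = 0.332) and Col3a1 at 0.16 (adjusted p = 0.584), and neither passed; the estimate for Col1a1 is imprecise (SE 0.27, with 8 of 10 old arrays above the young mean). Fibroblast markers rose by 0.39 (12 of 22 higher, 1 lower; camera adjusted p = 0.000189; adjusted p = 0.196 with an estimated correlation), including Fstl1 (1.23) and Vim (0.86). Valve and cartilage markers rose by 1.65, with 5 of 7 higher and 1 lower (camera adjusted p = 2.53e-06; adjusted p = 0.0684 with an estimated correlation). All 10 old arrays lay above all young ones for Comp (2.93), Cilp (2.06), Prg4 (2.17) and Cnmd (1.93). Of 18 listed valve and cartilage markers only 7 were tested, and Comp was above 4 in 10 old and 0 young arrays. With the index the shifts were 0.56 for matrix, 0.25 for fibroblast and 1.44 for valve and cartilage genes. Without the 7 arrays the shifts were 0.38 for matrix, 0.21 for fibroblast and 1.46 for valve and cartilage genes, each still called (adjusted p of at most 0.0362). In the sets the 3 lists ran from 0.32 to 0.94, from 0.08 to 0.62 and from 1.40 to 2.02.

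Genes of cardiac hypertrophy and the fetal heart rose by 1.10 as a list, with 9 of 16 higher and 0 lower (0.57 to 1.93 in the sets; camera adjusted p = 3.91e-05; adjusted p = 0.196 with an estimated correlation). Myh7, the slow myosin heavy chain of the fetal mouse ventricle, was 10.72 ± 0.79 in old and 8.12 ± 0.67 in young (SD, n = 10 each, adjusted p = 3.92e-06), and its change was 2.95 without the 7 arrays (adjusted p = 0.000257). The list was at 0.86 with the index and 0.60 without the 7 arrays, called in both. Fhl1 rose by 1.43 and Uchl1 by 1.06. Nppa, atrial natriuretic peptide, rose by 2.71 (adjusted p = 0.00213), but its adjusted p was 0.316 with the atrial index and 0.784 without the 7 arrays. Nppb rose by 0.59 (adjusted p = 0.0481), and 13 of the 20 fits that left out 1 array lost that call. The main contractile and pump genes did not pass the test. Myh6, the adult fast myosin, was 15.90 in both groups (difference −0.003, adjusted p = 0.98), at the top of the scale, where a change could be hidden. Atp2a2, the calcium pump of the sarcoplasmic reticulum, differed by 0.02 (SE 0.06, adjusted p = 0.867), and Acta1, skeletal actin, by −0.44, an imprecise estimate (SE 0.31, adjusted p = 0.346). Of 21 sarcomere genes, 1 rose (Tcap, 0.38) and 1 fell, the actin filament gene Lmod2 (−0.47), with a mean of −0.03 (−0.15 to 0.04 in the sets, 0.02 with the index, −0.01 without the 7 arrays; camera adjusted p = 0.405).

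Blood cell genes were higher in old. Of 7 erythroid and platelet markers, 6 rose and 0 fell, by a mean of 2.04 (1.29 to 2.76 in the sets; camera adjusted p = 1.86e-05; adjusted p = 0.196 with an estimated correlation), and the shift was 1.84 with the atrial index and 1.80 without the 7 arrays. The platelet genes Clec1b (4.16), Ppbp (3.53), Gp1bb (3.23) and Pf4 (1.53) rose, all but Ppbp with the 10 old arrays above all young ones. Alas2, the first enzyme of haem synthesis in red cell precursors, rose by 1.85. The 7 tested erythroid and platelet markers were part of 20 listed. Epicardial and mesothelial markers rose by 0.96 (5 of 7 higher, 0 lower; camera adjusted p = 0.00012; adjusted p = 0.124 with an estimated correlation), led by Gpm6a (3.03) and Efemp1 (1.56), with 0.36 to 1.30 in the sets, 0.565 with the index and 0.56 without the 7 arrays, called in both. Adipocyte markers rose by 1.27 with 3 of 8 called, including Scd1 (2.20), and B and plasma cell markers by 1.01 with 1 of 3 called, Ighm (1.79). Of 20 listed adipocyte and 23 listed B and plasma cell markers, 8 and 3 were tested. The camera adjusted p of these 2 lists was 0.0441 and 0.0485, and 0.429 and 0.299 with an estimated correlation. Without old replicate 8, the highest array for both lists, the shifts were 0.91 and 0.76, and of the 20 fits that left out 1 array 8 lost the adipocyte call and 9 the B cell call. Neither list was called with the index (1.04 and 0.60; adjusted p = 0.157 and 0.298) or without the 7 arrays (0.67 and 0.48; 0.157 and 0.202), nor with the set block, which left the shifts unchanged (0.133 for both). Over the sets they ran from 0.52 to 2.65 and from 0.35 to 2.12.

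Heat shock and unfolded protein response genes fell by 0.39, with 9 of 31 lower and 1 higher (camera adjusted p = 0.00212; adjusted p = 0.282 with an estimated correlation). Hspa1a was 4.46 ± 0.51 in old and 7.63 ± 2.15 in young (SD, n = 10 each, adjusted p = 0.00136), and the young arrays ran from 4.41 to 10.65. The chaperone gene Dnaja1 fell by 1.19. The list's shift was −0.46 with the atrial index and −0.49 without the 7 arrays, and it was 0.005 in 1 of the 5 sets and −0.43 to −0.64 in the other 4. Cytosolic ribosomal genes rose by 0.16 (7 of 31 higher, 0 lower; 0.03 to 0.31 in the sets; camera adjusted p = 0.000154; adjusted p = 0.314 with an estimated correlation), including Rpsa (0.37). Proteasome genes fell by 0.12, with 1 of 31 called, Psmb7 (−0.39; −0.04 to −0.26 in the sets; camera adjusted p = 0.00546; adjusted p = 0.314 with an estimated correlation). Without the 7 arrays neither the ribosomal (0.09) nor the proteasome list (−0.04) was called (adjusted p = 0.157 and 0.277); with the index both were, at 0.11 and −0.10. Cdkn1a, a cell cycle inhibitor gene, was at 0.49 (adjusted p = 0.223). Cdkn2a had a mean of 2.21 on the log2 scale and was below the filter, and C4b was not analysed here.

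**Figure D4:**
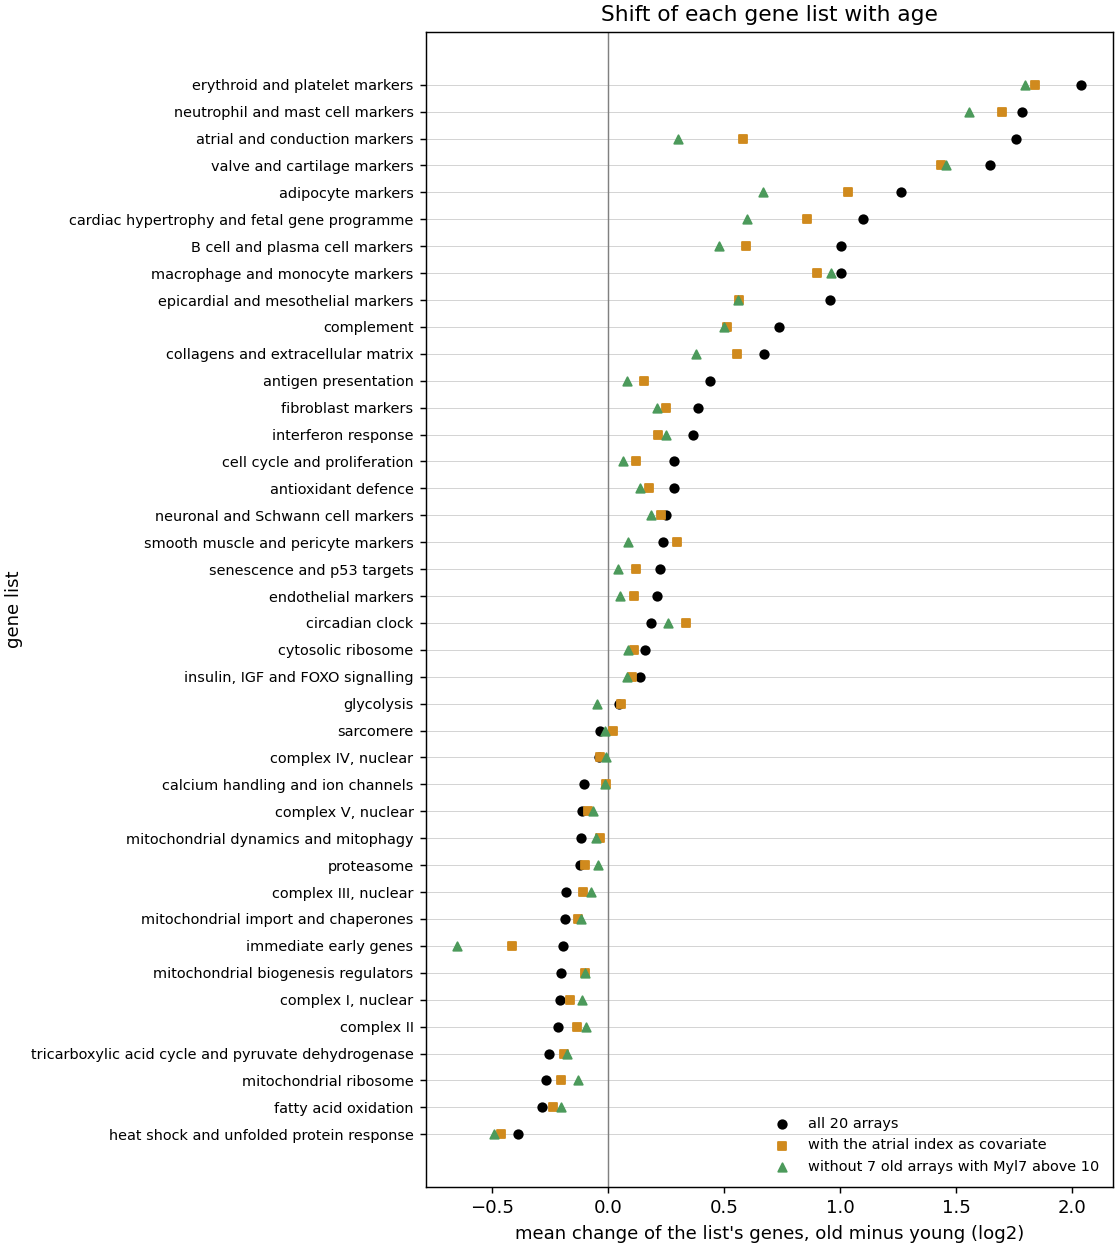
Each point gives the mean log2 change of a gene list, old minus young, on the horizontal axis, for 40 lists on the vertical axis; circles use all 20 arrays, squares add the atrial index as a covariate and triangles leave out 7 old arrays with Myl7 above 10. The atrial and conduction list moved from 1.76 to 0.58 and 0.30, the macrophage list from 1.004 to 0.90 and 0.96, and fatty acid oxidation from −0.28 to −0.23 and −0.20.

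In all, camera called 28 of 40 lists, 15 higher and 13 lower in old. With an estimated correlation it called 0 (9 at an unadjusted p under 0.05), and fry called 30. A two-sided permutation test of each list's mean per animal called 31 lists, 20 higher and 11 lower, and 32 when arrays were exchanged within sets. The set block left 26 camera calls, without the adipocyte, B cell and mitochondrial dynamics lists and with the endothelial list (adjusted p = 0.0323). With index and sets together 17 were left; complexes II, III and V, import, dynamics, proteasome, calcium handling, antigen presentation, interferon, B cell, adipocyte and atrial genes lost the call, and immediate early genes gained it. Variation between animals did not clearly differ: the median over genes of the log2 ratio of old to young standard deviations was 0.17, and 0.06 without old replicate 8.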

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

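In each group of 10 arrays, the highest and the lowest value of 120 genes and 42 list scores named in the text were compared with the nearest other array, and values whose gap exceeded Dixon's 95% limit are given here. Of the 324 groups tested, 30 values passed; chance alone gives about 1 in 20, or about 16. A value given here is one that lies far from the other 9 arrays of its group. Some of the genes were picked only after their values were seen. Old replicate 8 had 10 of them.

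Old replicate 8 was the lowest old array for the nuclear respiratory chain score (12.87), the complex I score (12.73), the complex V score (13.25) and Cox7a1 (13.09). It was the highest old array for the adipocyte marker score (11.08), the cell cycle score (7.784), Scd1 (12.89), Ighm (10.60), the immunoglobulin joining chain gene Jchain (10.68) and the T cell receptor complex gene Cd3d (8.379). Jchain, Cd3d and Adipoq, an adipocyte hormone gene at 12.02 in this array, were chosen after their values were seen.

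Old replicate 9 was the highest old array for the erythroid and platelet score (11.60), Pf4 (12.14) and Gp1bb (10.76), and the lowest for Acaa2 (11.49). Old replicate 1 was the lowest old array for the collagen and matrix score (7.562) and Col3a1 (10.03). Old replicate 10 was the lowest for Myh7 (8.611), with the next old array at 10.48. Fhl1 was highest in old replicate 5 (13.46), and the insulin, IGF and FOXO score in old replicate 6 (8.30).

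Among young arrays, replicate 14 was the highest for Myl4 (5.164) and Ccl8 (4.498), replicate 20 for Car3 (6.967), replicate 11 for Fmod (4.214), replicate 12 for Slc4a1 (5.962) and replicate 15 for Bmp10 (2.709). Replicate 18 was the lowest for Bex1 (5.766), replicate 13 for Pdhb (13.19), replicate 11 for the water channel gene Aqp1 (10.39), and replicate 19 for Lcn2 (2.72) and Ighm (5.168).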

How the results depend on the processing

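No paired analysis was possible because the old and young groups share no replicate numbers. The set block matches arrays by sets found in their values, which follow the order of the replicate numbers in part. The main counts were 1732 genes (1037 higher, 695 lower) and 28 lists, with a nuclear respiratory chain difference of −0.15. The alternatives with the array sets, the atrial index or fewer old arrays were chosen after seeing the data; the others were set beforehand. Causes of the changes were not tested except where the alternative's construction gives them.

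Scaling moved the falls to 1072 (quantile normalization) and 1119 (median centring). Those settings shifted the median change of all genes from 0.009 to −0.06 in both. Without a filter, more genes were tested (18194) and 4349 changed, 3047 lower. Of the lists, 9 were then weaker and 5 stronger than in the main fit. A fold of at least 1.5 left 782 genes (590 higher, 192 lower), and an adjusted p under 0.01 left 857 (563 and 294). The set block gave 3344 genes (1798 higher, 1546 lower). The atrial index gave 347 (261 and 86) with 18 lists, index and sets together 579 (404 and 175) with 17 lists, 3 old arrays against 10 young 272 (209 and 63) with 16 lists, and those arrays with the set block 451 (287 and 164) with 15 lists. Part of the last losses is sample size: 100 random choices of 3 old arrays gave 182 to 1948 genes (median 720.5), 7 of them with 272 or fewer. Camera with an estimated correlation called 0 lists.

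The nuclear respiratory chain difference was −0.11 (p = 0.068) with the index, −0.0717 (p = 0.148) with index and sets, and −0.076 (exact permutation p = 0.0979) without the 7 arrays; it kept its call with quantile normalization, median centring, both other filters, both other choices of probe sets, the set block and each fit that left out 1 array, and was not run with array weights, the RNA quality covariate, trend and robust settings, or the 7 arrays left out together with the set block. The mitochondrial DNA score, 1 gene, was −0.07 and moved to −0.0268 (p = 0.444) after quantile normalization and to −0.14 (p = 1e-04) after median centring, while the nuclear minus mitochondrial DNA difference went from −0.09 (p = 0.155) to −0.13 (p = 0.00886). Tbx5 went from 1.66 to −0.00817 without the 7 arrays (adjusted p = 0.989).

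Leaving out each array in turn gave 1391 to 1830 genes, 853 to 1092 higher and 538 to 777 lower, 23 to 29 lists, a respiratory chain difference of −0.17 to −0.12, a mitochondrial DNA score of −0.08 to −0.05, a nuclear minus mitochondrial DNA difference of −0.11 to −0.04 and a spread ratio of 0.06 to 0.25. Of the genes considered for naming, 86 lost their call with the index, 73 with index and sets, and 97 besides Tbx5 without the 7 arrays, with median changes of 77.3%, 70.8% and 60.6% of the size over all arrays, and 10, 8 and 9 of them as large or larger; the set block lost 0 and added 14. Low signal limits genes under the filter, and saturation the brightest ones. Array quality had no alternative.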

Other observations

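The explanations weighed in this part were tested, and their tests chosen, only after the results were seen.

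Several groups not described so far held genes that moved in opposite directions. In glycolysis, 5 of 18 genes rose and 4 fell, with a mean of 0.05 (camera adjusted p = 0.909). The ubiquitous isoform genes Pgam1 (0.81) and Hk1 (0.62) were higher in old, and Eno3, the muscle enolase gene (−0.38), and Pfkfb2, a heart isoform (−0.88), were lower. Among 24 calcium handling and channel genes, 2 rose and 4 fell, with falls of the potassium channel genes Kcnip2, at 8.35 ± 0.35 in old and 9.35 ± 0.28 in young (SD, n = 10 each, adjusted p = 2.65e-05), and Kcnd2 (−0.81), and the calcium-binding protein gene Hrc (−0.60), and a rise of the potassium channel gene Kcnh2 (0.97). That list was called by camera (mean −0.10, adjusted p = 0.0308; adjusted p = 0.389 with an estimated correlation), and its score did not pass the permutation test (adjusted p = 0.186). It was at −0.007 with the atrial index and −0.0098 without the 7 old arrays with Myl7 above 10, not called in either (adjusted p = 0.387 and 0.377), 3 of the 20 fits that left out 1 array lost it, and the sets ran from 0.02 to −0.21. Of 24 antioxidant genes, 6 rose and 5 fell (mean 0.28, camera adjusted p = 0.2), with Gpx3 at 2.33 and Mt2 at 1.23. Of 24 endothelial genes, 7 rose and 3 fell (mean 0.21, camera adjusted p = 0.0565), with the clotting factor gene Vwf at 2.27, Tmem100 at 0.82 and the water channel gene Aqp1 at −1.16.

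Of 25 interferon response genes, 7 rose and 1 fell (mean 0.37, camera adjusted p = 0.0198; adjusted p = 0.389 with an estimated correlation), among them Ifi27l2a (1.42). The interferon list was not called with the atrial index (adjusted p = 0.346) or without those 7 old arrays (0.145). The clock repressor gene Bhlhe40 (0.89, adjusted p = 0.000317), the clock output gene Dbp (1.30, adjusted p = 0.0231) and the clock repressor gene Nr1d1 (0.93, adjusted p = 0.0017) were higher in old, in a list of 18 with 3 rises and 0 falls (mean 0.18, camera adjusted p = 0.385). Of 19 senescence and p53 genes 5 rose and 1 fell, with the stress gene Sesn1 at −0.82, Phlda3 at 1.19 and the cell cycle inhibitor gene Cdkn2c at 0.93. Igfbp5, of the insulin list, rose by 1.29. Camera did not call the lists for senescence and p53 targets (mean 0.22, adjusted p = 0.245), cell cycle (0.29, 0.385), smooth muscle and pericytes (0.24, 0.645), immediate early genes (−0.19, 0.107), insulin, IGF and FOXO signalling (0.14, 0.696) or neurons and Schwann cells (0.25, 0.184). The permutation test per animal did call 5 lists that camera did not: antioxidant (adjusted p = 0.0004), senescence (0.000844), insulin (0.00178), neuronal (0.00477) and endothelial genes (0.0158). For the insulin and neuronal lists the median change was negative (−0.07 and −0.001) while the mean was positive. Camera called the immediate early list lower with the atrial index (−0.41, adjusted p = 0.00388) and without those 7 old arrays (−0.65, adjusted p = 7.97e-06), but 2 of the 5 sets went the other way, 2 of the 3 old arrays left come from the set at −0.77, and over all arrays adjusted p was 0.612 with an estimated correlation. Over the sets the lists ran from −0.004 to 0.09 (glycolysis), 0.19 to 0.58 (antioxidant), −0.002 to 0.49 (endothelial), 0.19 to 0.58 (interferon), −0.14 to 0.57 (clock), 0.02 to 0.34 (senescence), 0.03 to 0.95 (cell cycle), 0.03 to 0.44 (smooth muscle), −0.77 to 0.15 (immediate early), 0.06 to 0.21 (insulin) and 0.13 to 0.38 (neuronal). Without old replicate 8 the cell cycle shift was 0.11.

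Atrial transcripts in old arrays are the first pattern. Over the 9 old arrays with Myl7 above 4, Sln followed Myl7 with a slope of 1.09 ± 0.06 (SE) on the log2 scale. Myl4 had a slope of 1.02 ± 0.05 (SE), as in tissue holding these transcripts in a fixed ratio. The slopes of Nppa, Stard10 and Tbx5, already above the floor in young, were 0.498, 0.469 and 0.422. Dkk3, of the atrial list, had a slope of 0.683, and Upk3b, of the epicardial and mesothelial list, 0.373. Bmp10, another atrial gene, was above 8 in old replicates 5, 6 and 8 and 2.39 to 2.40 in old replicates 3, 4 and 10. Irx4, a ventricular gene, was 0.58 lower in old (permutation p = 0.0281, adjusted p = 0.0333), lowest in old replicates 8 and 9 (4.86 and 4.98) and at 6.71 in old replicate 10, which had the highest Myl7. A single fetal gene programme raising Myl7 and Myh7 together is argued against by their rho of −0.697 over the 10 old arrays (permutation p = 0.0303, adjusted p = 0.0341), but weakly: leaving out each old array in turn rho stayed negative, between −0.583 and −0.817, with p between 0.0108 and 0.108, and Pearson's r was −0.383 (p = 0.215), and −0.276 without the 2 farthest arrays. Atrial tissue in the old samples cannot be told apart from the groups, since no young array had Myl7 or Sln above 4. The test asked for slopes near 1 for Sln, Myl4, Dkk3 and Upk3b, which Dkk3 and Upk3b missed. The unequal slopes do not decide it, as Nppa, Stard10 and Tbx5 start above the floor in young and Upk3b is an epicardial marker. Neither reason holds for Dkk3, which was above 4 in 0 young arrays and had a slope of 0.683 ± 0.101 (SE). Its ratio to Myl7 within atrial tissue was not measured. Bmp10 does not decide it either, since its spread within atrial tissue was not measured. Expression of atrial genes in old ventricles, independent of Myh7, stays open and was not tested. Myh7 lay 2.95 above young in the 3 old arrays with Myl7 under 10 (exact permutation p = 0.0035).

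Lower nuclear mitochondrial transcripts in old are the second pattern. Each array set holds as many old as young arrays, so an additive set effect cancels from the difference by design, and the score was lower in each of the 5 sets. Atrial tissue as the whole cause cannot be told apart from age: without the 7 old arrays the difference was −0.1158 for all nuclear mitochondrial lists (exact permutation p = 0.0245) and −0.076 for the respiratory chain (p = 0.0979), but matched within sets, with 3 old and 4 young arrays, it was −0.09 and −0.05 (exact p = 0.167 for both, smallest possible 0.0556), and with index and sets together p was 0.0736 and 0.148. Dilution of cardiomyocyte RNA by cells whose markers rose is argued against as the whole cause: 194 mitochondrial genes differed by −0.23 and 11 sarcomere genes of like level by −0.04, a gap of −0.1959 that was negative in all 5 sets (exact within-set p = 0.00103), as in the 2 other level windows tried (−0.18 and −0.20, p = 0.00129 and 0.000257), though without the sets the 3 windows gave p = 0.103, 0.162 and 0.0303, and the sets were found on these values. Age itself stays among the open explanations, untested.

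Higher platelet transcripts in old are the third pattern. The mean of Ppbp, Pf4, Gp1bb, Clec1b and Alox12 was 7.87 ± 1.30 in old and 4.94 ± 0.34 in young (SD, n = 10 each; permutation p = 1e-05, the smallest possible), and that of the red cell genes Slc4a1 and Alas2 8.79 ± 2.15 and 6.66 ± 0.32 (p = 0.00017); Alox12 and Slc4a1 were chosen after their values were seen. More whole blood left in the old hearts could not be tested at equal red cell content. In the 4 old arrays whose red cell score was no higher than the highest young one, the platelet score was 2.128 above young (exact permutation p = 0.000999). Their red cell score was also 0.49 above young (exact permutation p = 0.03). The cut was set by young replicate 12 (7.363), with the next young array at 6.939. Old replicates 2, 6 and 7 had red cell scores of 7.267 to 7.324. Old replicate 10 (6.684) had the lowest old platelet score (6.184, against a highest young one of 5.565). The comparison therefore does not decide it. The 2 scores did rise together over the 10 old arrays (Spearman's rho 0.806, permutation p = 0.00724; Pearson's r 0.782, p = 0.00774; r = 0.58 without the 2 farthest), so blood may add to some arrays. More whole blood stays open, as do platelets held in the tissue and age itself, which were not tested.

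Whether chance groupings of the arrays give as much was asked with 100 splits of the 20 arrays, the real one included. Chance can be excluded for the number of genes: 1 split, the real one, reached 1732, and the highest other split had 1. With the set block 1 split reached 3344, the highest other having 2. The list count is less secure. 2 of 100 splits reached 28 lists, the highest other having 28 and the median split 10, and with splits inside the sets 7 of 100 reached the real 26, the highest other having 27, so there chance cannot be excluded. Camera at its preset correlation thus called many lists between arbitrary groups of these arrays. The permutation test treats the animal as the replicate but asks another question, whether a list's mean moved at all. It called 31 of 40 lists and was not put through these splits. For the spread, 38 of 100 splits reached 0.17 in size, the highest other being 0.38, and chance cannot be excluded.

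Within the 10 old arrays the atrial index was set against 42 scores. For the atrial list the outcome was fixed in advance and is no test. Myl7 and Sln, which form the index, are on that list, and its tested member Myl4 followed Myl7 (Pearson's r 0.99). The atrial list (Pearson's r 0.922, permutation p = 0.00022, adjusted p = 0.00924; Spearman's rho 0.952, p = 0.00011, adjusted p = 0.00462; r = 0.943 without the 2 farthest arrays) passed the adjustment in both. The epicardial and mesothelial list passed it for r (0.917, p = 0.00106, adjusted p = 0.0223; 0.898 without the 2 farthest) and not for rho (0.83, p = 0.00491, adjusted p = 0.0687). The score of all nuclear mitochondrial lists did not (r = −0.391, p = 0.278, adjusted p = 0.554; rho −0.333, p = 0.348, adjusted p = 0.58; r = −0.62 without the 2 farthest). The complement list passed for neither, though its rho was about as high as that of the epicardial list. Its rho was 0.842 (permutation p = 0.00343, adjusted p = 0.0687) and its r 0.766 (permutation p = 0.0108, adjusted p = 0.151).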
